A study of Mus musculus with 24 samples.

How the data were processed

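RNA of sorted CD4 and CD8 T cells from spleen and thymus of young and old mice was hybridised to two-colour 44K arrays, with the sample in Cy3 and a reference in Cy5 on all 24 arrays and no dye swap. The deposited scanner files were made with Agilent Feature Extraction 9.5.1.1, and per the file headers they give spot and background signals as intensity in each channel. The deposited LogRatio column is in log10 and sets Cy5 over Cy3, so its sign was turned wherever a ratio is given. The deposited series matrix values are in log10. How the authors computed them is not stated in the labels. On the 20 arrays of the first scan day they correlated at 0.999 across probes with Cy3 minus Cy5 plus the mean Cy5 of the probe, all in log10, and on the 4 arrays scanned later at 0.958, and genes and probes are not independent replicates. The step used for the later slide stays unknown, and the matrix served only as an alternative.

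Spots that the scanner software marked as not uniform or as outliers were left out, between 0.546% and 4.56% of an array's spots. Median background was subtracted from mean signal with the normexp model (offset 50) of limma 3.58.1 in R 4.3.3, each array was normalised by loess, and replicate spots were averaged. The unit of every comparison is log2 of sample over reference. A probe was kept when its Cy3 signal stood well above background on at least 3 of the 24 arrays, and a gene was represented by its brightest kept probe. The 39429 probes, on 43020 spots that are not among the 1377 controls, were named from the reference table of mouse genes (assembly GRCm38.p6), 26055 by accession, 3195 by symbol and 930 by an older symbol, and 9249 kept the name in the file. This gave 24139 tested genes, 16005 of them with a current symbol. No coordinate is printed, since the design file uses the build NCBI37 which the reference table does not share.

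Slide, position and scan day were read from the file headers and names. Print lot was inferred from the leading part of the slide barcode, and arrays that share it are taken here as 1 lot. The 24 arrays lay on 6 slides of 4. Slides 1, 2 and 3 held young samples and slides 4, 5 and 6 old samples, and slide 6, with old thymus CD4 replicate 3 and the old thymus CD8 samples, was scanned later and at another scanner range. Saturated Cy5 probes numbered 1453 to 1540 on its arrays, and the other 20 arrays had none. The labels describe the reference alike for all arrays, and whether the later slide received the same preparation was not tested. Cy3 signal stood well above background for 52.0% to 69.6% of the probes of an array and Cy5 signal for 52.9% to 64.7%, and the number of arrays limits the precision.

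A linear model with 1 mean for each of the 8 groups was fitted to all arrays with limma (lmFit and eBayes), and 10 comparisons were tested, 4 of age, 2 of tissue, 2 of lineage and 2 of age by tissue. Each comparison was adjusted over its genes by Benjamini-Hochberg, with a threshold of 0.05. Tissue and lineage comparisons average the ages with equal weight. Fixed lists of T cell states, of pathways linked to ageing and of markers of other cell types, 30 in all, were tested with camera of limma where at least 5 members were measured, with a preset correlation of 0.01 and again with an estimated one, and adjusted over the lists of a comparison. Of the list calls, 8 held with an estimated correlation, namely the double-positive thymocyte list in both tissue comparisons, in lineage in the thymus, in age in thymus CD8 and in age by tissue in CD8, the thymocyte marker list in both tissue comparisons, and the chromatin modifiers in tissue in CD4. The reference channel was tested in the same way after quantile normalisation.

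The groups, comparisons, tests, lists, the rule for named genes and the alternatives named first below were fixed before the data were examined. The rule takes, among genes with a current symbol that passed and whose arrays did not overlap (within each age for tissue and lineage, and without this condition for age by tissue), the 10 largest rises and the 10 largest falls, up to 4 members with the smallest p from each list described, and Cd4, Cd8a, Cd8b1, Rag1, Rag2, Dntt, Cd24a, Ccr9, Klf2, S1pr1, Xist, Ddx3y and Eif2s3y. Probes of 1 gene that differ in sign are pointed out.

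Replicate numbers were checked for pairing. Residuals of arrays with the same number correlated above 0.1 in all 3 pairs of 1 age comparison, spleen CD4, at 0.121 to 0.222, and arrays with the same number there also share the position on a slide, so that a blocked value stands beside that count. For tissue in CD8, 5 of 6 pairs correlated above 0.1, at up to 0.413, and the count was 8847 with a replicate block against 9044. Alternatives were Agilent's processed signals, median centring, quantile normalisation between arrays, the Cy3 channel alone, the series matrix, no or a stricter filter on dim probes, the mean over probes, a threshold of 1.5-fold, trend and robust eBayes, a replicate block, print lot, slide as random or fixed block, a fit to the groups compared alone, and leaving out each array. Added after the data were seen were scan day as a covariate, genes with no saturated spot, and fits without the later slide or without both old spleen replicates 3. The steps were tested on simulated data of 21722 genes, of which 67 had a known log2 change of 1, 67 of 2 and 66 of 3. At a log2 change of 2, 100% of the changed genes were recovered for age in spleen CD4, 100% for tissue in CD4 and 88.1% for age by tissue in CD4, and at a log2 change of 1 the shares were 76.1%, 89.6% and 46.3%. Unchanged genes called numbered 11, 15 and 5. The simulated noise was independent between genes and arrays and held no slide effect, so these shares do not cover the slides of the real data. Figures were drawn with matplotlib.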

Results

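Gene expression was measured with 24 two-colour arrays in CD4 and CD8 T cells from the spleen and the thymus of young and old C57BL/6 mice, which makes 8 groups of 3 arrays. The young mice were 8 weeks old (13 mice) and the old mice 79 to 121 weeks old (22 mice), of both sexes. Splenocytes were depleted of B cells with anti-CD19 beads and sorted as CD44-low, CD62L-positive cells, and mature thymocytes were sorted as lineage-negative, CD44-low cells. The labels do not say whether the 3 samples of a group came from separate animals, so every p-value measures only the spread between samples. Each Cy3-labelled sample was hybridised with a Cy5-labelled reference that the labels describe alike for all arrays, a mix of resting and CD3/CD28-stimulated T cells. Cy3 signal stood well above background for 52.0% to 69.6% of the probes of an array, and the number of arrays limits the precision. Young and old samples shared no slide, and the 3 old thymus CD8 arrays and old thymus CD4 replicate 3 lay on a slide that was scanned later than the other 5. Differences are given in log2 units ± SE, from 3 arrays against 3 in an age comparison and 6 against 6 in a tissue or lineage comparison, unless a gene had missing values. Where every array of 1 group was too dim for a gene, its level there was put at the dimmest signal still well above background, and the change in Cy3 signal is given as at least that many fold.

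The abbreviations that go with the labels are ones the field also uses in other senses, so the words spleen and thymus were first compared with marker genes. Thymocyte markers, which include the recombination and pre-T cell receptor genes, were lower in spleen than in thymus in each of the 4 pairs of groups. The mean over arrays of the list's median differed by -0.67 in young CD4, -1.80 in young CD8, -1.54 in old CD4 and -2.67 in old CD8 cells, and the arrays did not overlap in any of these pairs. Chance alone separates 3 arrays from 3 in 10% of comparisons. Genes of naive peripheral cells and of egress from the thymus were higher in spleen by 0.29, 1.06, 0.14 and 0.76 in the same order, with overlapping arrays in the old CD4 pair. Cd8a, a chain of the CD8 co-receptor, had log2 ratios to the reference of -1.90 ± 0.05 (SD, n = 3) in young spleen CD4 and 0.83 ± 0.06 (SD, n = 3) in young spleen CD8 cells. Old spleen CD4 replicate 3 was an exception among the CD4 samples of the spleen, with a Cd8a value of 0.38 against -0.70 and -1.52 in replicates 1 and 2. All groups were kept as labelled.

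**Figure D1:**
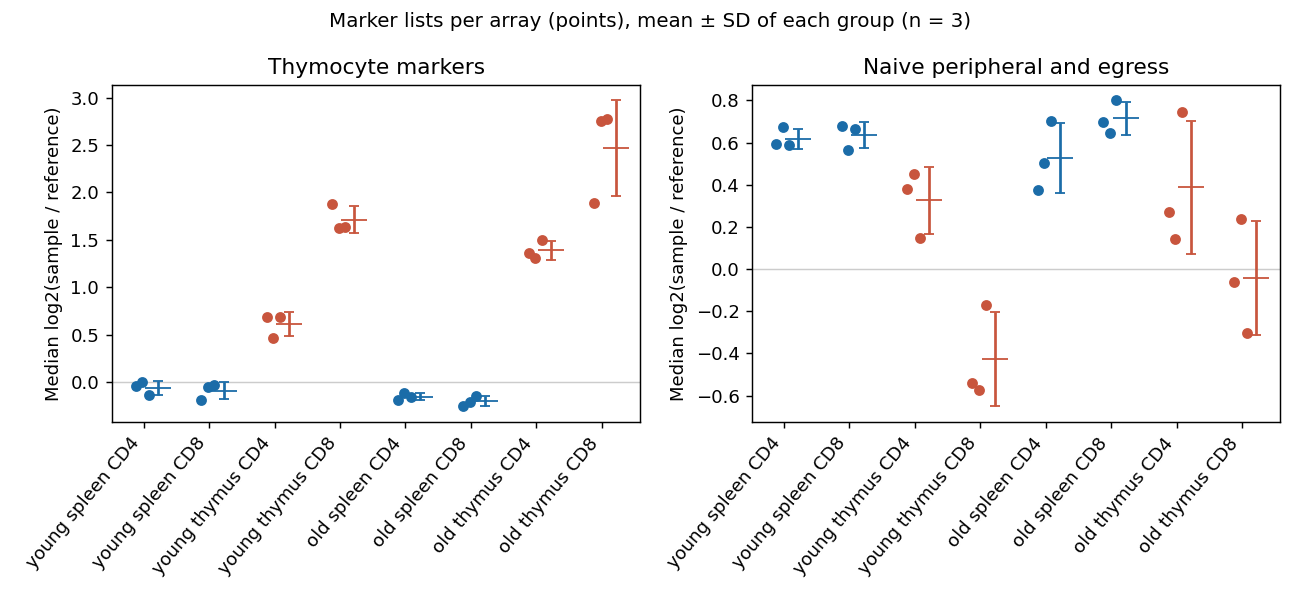
Median log2 ratio to the reference of the thymocyte marker list (left) and of the naive peripheral and egress list (right), where each point is 1 array, each line the mean of a group and each error bar its SD (n = 3). The thymocyte medians of all 12 spleen arrays lie below those of all 12 thymus arrays.

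The series title asks how T cells change from thymus to periphery, and the first comparison set spleen against thymus CD4 cells, averaged over both ages. Genes of immature thymocytes were lower in spleen. Sox4, a transcription factor of developing lymphocytes, fell by 3.33 ± 0.23, adjusted p = 3.82e-08, and Dntt, which adds nucleotides where receptor gene segments join, fell by 2.54 ± 0.18, adjusted p = 6.24e-08. Itm2a, a membrane protein induced during positive selection, fell by 2.81 ± 0.28, adjusted p = 2.88e-06. Higher in spleen were Cd55, which protects cells from complement, by 2.49 ± 0.12, adjusted p = 3.36e-10, and Dapl1 by 2.56 ± 0.24, adjusted p = 1.12e-06. Among 19 measured thymocyte markers, 12 fell and 7 did not pass, and 16 fell when adjusted over the list alone. Of the 14 genes typical of double-positive thymocytes, 9 fell, among them Aqp11 by 1.88 ± 0.18 and Ptcra, the pre-T cell receptor alpha chain, by 1.33 ± 0.12, while 5 did not pass and 10 fell adjusted over the list alone. Chromatin modifiers gave 2 rises, 17 falls and 32 genes that did not pass among 51 (4 and 23 adjusted over the list alone), and the DNA methyltransferase Dnmt3a fell by 0.93 ± 0.13, Satb1 by 0.95 ± 0.15 and Tet1 by 1.59 ± 0.24. All 3 lists moved as a whole (camera, adjusted p = 1.54e-15, adjusted p = 7.63e-10 and adjusted p = 1.42e-06), and these calls held with an estimated correlation.

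Immediate early and activation genes were higher in spleen CD4 cells. 13 of 30 rose, 1 fell and 16 did not pass (17 rose and 2 fell adjusted over the list alone), with Jun at 1.76 ± 0.30, Klf6 at 1.30 ± 0.15 and Cd69 at 1.18 ± 0.20. The list median was 0.46 (adjusted p = 6.59e-08, but adjusted p = 0.251 with an estimated correlation). Markers of B cells, which the beads were meant to remove, moved the same way, with 12 of 22 risen and 10 not passed (15 risen adjusted over the list alone), a median of 1.02 (adjusted p = 3.47e-08, but adjusted p = 0.417 with an estimated correlation), Cd79b at 1.51 ± 0.31 and Ebf1 at 1.66 ± 0.41. Klf2, which drives exit from the thymus, rose by 0.46 ± 0.11, adjusted p = 0.00971, and Sell, the homing receptor L-selectin, by 0.70 ± 0.09, adjusted p = 2.94e-05. S1pr1, the receptor for egress, differed by 0.06 ± 0.18 and Cd4 by -0.45 ± 0.34, and neither passed. With the Cy3 channel alone S1pr1 was higher in spleen by 1.24 (limma, adjusted p = 0.00111), while Cd4 differed by -0.65 and did not pass. Whether S1pr1 differs between the tissues in CD4 cells thus depended on the reference channel. In all, 2949 genes passed an adjusted p of 0.05, 1393 higher and 1556 lower in spleen, a balance that turned with Agilent's processed signals (1433 and 1318), after median centring (309 and 300), with slide as a random block (837 and 809) and without old spleen CD4 replicate 3 (1263 and 1184). The count was 609 after median centring in place of loess, 1646 with slide as a random block, 190 with slide as a fixed block and 1037 when at least 1.5-fold was also required.

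The same question was put to CD8 cells, and spleen again showed lower thymocyte genes. Rag1 and Rag2 encode the recombinase of receptor genes. Rag1 fell by 5.20 ± 0.52, adjusted p = 9.66e-07, although only 1 old spleen array gave a value for it, and Rag2, too dim on every spleen array, was at least 12.7-fold lower (adjusted p = 3.09e-12). Sox4 fell by 4.80 ± 0.23, adjusted p = 5.96e-12 and Rrm2, a subunit of the enzyme that makes deoxynucleotides, by 4.66 ± 0.23, adjusted p = 7.21e-12. Highest in spleen were Dapl1, up by 3.63 ± 0.24, adjusted p = 4.87e-10, and Cd55, up by 2.88 ± 0.12, adjusted p = 1.04e-12. Of 15 double-positive thymocyte genes 13 fell and 2 did not pass (14 fell adjusted over the list alone), with Ptcra, too dim on 5 of 6 spleen arrays, at -3.71, Rorc at -3.64 and Arpp21 at -2.82. Of 19 thymocyte markers 16 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. Both lists moved as a whole (camera, adjusted p = 9.08e-14 and adjusted p = 4.57e-11), and the calls held with an estimated correlation. Cell cycle genes were lower in spleen, with 39 of 41 fallen and 2 not passed, both over all genes and adjusted over the list alone. Among them Uhrf1 fell by 4.38 ± 0.26, Prc1 by 2.51 ± 0.15 and Rrm1 by 2.43 ± 0.17, and the list median was -1.69 (adjusted p = 3.69e-26, but adjusted p = 0.228 with an estimated correlation).

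Genes of naive peripheral cells and egress were higher in spleen CD8 cells, with 20 of 29 risen, 2 fallen and 7 not passed, the same as adjusted over the list alone. Klf2 rose by 1.44 ± 0.11, adjusted p = 4.98e-09, S1pr1 by 1.35 ± 0.18, adjusted p = 7.28e-06, Sell by 1.28 ± 0.09 and the integrin chain Itgb7 by 1.82 ± 0.14. Members of the list had a median of 0.64 (adjusted p = 1.19e-06, but adjusted p = 0.234 with an estimated correlation). Immediate early and activation genes gave 26 rises and 4 genes that did not pass among 30 (28 rises and 1 fall adjusted over the list alone), with Cd69 at 2.45 ± 0.20 and Klf6 at 2.18 ± 0.15. The list had a median of 0.91 (adjusted p = 3.64e-11, but adjusted p = 0.127 with an estimated correlation). Interferon response genes gave 23 rises, 1 fall and 20 that did not pass among 44 (25 and 1 adjusted over the list alone), with Ifi203 at 1.13 ± 0.12 and Ifi35 at 1.05 ± 0.07. The median of the list was 0.34 (adjusted p = 7.97e-06, but adjusted p = 0.38 with an estimated correlation). In all 9044 genes passed, 4590 higher and 4454 lower in spleen, and the balance turned with scan day (2545 and 3390), with slide as a fixed (1296 and 1976) or random block (3184 and 3457), without the later slide (2941 and 4044), at 1.5-fold (2039 and 2150) and with 4 arrays left out in turn. The count was 5935 with scan day as a covariate, 3272 with slide as a fixed block and 4189 when at least 1.5-fold was also required, and no slide held both tissues of 1 lineage.

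The comparison of CD8 with CD4 cells of the spleen shows which genes part the lineages outside the thymus. Cd8a was higher in CD8 cells by 2.06 ± 0.28, adjusted p = 0.000787 and Cd8b1, the other chain of the co-receptor, by 1.95 ± 0.23, adjusted p = 0.000314. Klrd1, a receptor of cytotoxic cells, rose by 1.64 ± 0.28, adjusted p = 0.00539 and Itgae, an integrin chain that binds epithelium, by 1.38 ± 0.24, adjusted p = 0.00628. St8sia6, a sialyltransferase, fell by 2.81 ± 0.35, adjusted p = 0.000447, and Zbtb7b, the factor that sets the CD4 fate, by 1.30 ± 0.29, adjusted p = 0.0411. Cd4 itself differed by -0.75 ± 0.34 and did not pass. Of 20 CD8 lineage genes 6 rose and 14 did not pass (10 rose and 1 fell adjusted over the list alone, list median 0.62, adjusted p = 5.82e-14, but adjusted p = 0.119 with an estimated correlation). Of 15 CD4 lineage genes 2 fell and 13 did not pass (8 fell adjusted over the list alone, list median -0.49, adjusted p = 6.04e-11, but adjusted p = 0.119 with an estimated correlation). Regulatory T cell genes gave 3 falls, 1 rise and 13 that did not pass among 17 (6 and 1 adjusted over the list alone), with Foxp3, their lineage factor, at -1.39 ± 0.28, Lrrc32 at -1.10 ± 0.20 and Ikzf4 at -0.98 ± 0.18 (adjusted p = 5.47e-06, but adjusted p = 0.29 with an estimated correlation). B cell markers, of which all 22 stayed above an adjusted p of 0.05 in limma, had a list median of -0.60 and moved with the CD4 and regulatory genes (adjusted p = 6.13e-07, but adjusted p = 0.522 with an estimated correlation).

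In the spleen 178 genes parted CD8 from CD4 cells, 86 higher and 92 lower in CD8. With the Cy3 channel alone the split was 107 higher and 61 lower, with slide as a fixed block 69 and 22, without old CD4 replicate 3 it was 166 and 386, and without both old replicates 3 127 and 277. The balance also turned with a replicate block (78 and 77) and with 7 arrays left out in turn. The count was 388 with the series matrix values, 338 with scan day as a covariate, 91 with slide as a fixed block, 41 after median centring and 526 without the later slide. Left-out arrays moved it to 111 (young CD4 replicate 2), 104 (old CD4 replicate 2), 552 (old CD4 replicate 3) and 113 (old CD8 replicate 1), and it was 404 without old CD4 and old CD8 replicate 3.

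In the thymus the lineage comparison asks the same of cells that had not yet left it. Cd8a was higher in CD8 cells by 2.91 ± 0.28, adjusted p = 2.66e-07, Cd8b1 by 2.56 ± 0.23, adjusted p = 1.52e-07 and Rrm2 by 2.98 ± 0.23, adjusted p = 1.77e-08. Endou, a gene of double-positive thymocytes, rose by 3.20 ± 0.13, adjusted p = 8.21e-12. Itm2a fell by 2.57 ± 0.28, adjusted p = 1.31e-06, St8sia6 by 2.58 ± 0.35, adjusted p = 1.57e-05 and Icos, a co-stimulatory receptor, by 2.12 ± 0.23, adjusted p = 1.39e-06, while Cd4 differed by -0.70 ± 0.34 and did not pass. Double-positive thymocyte genes were higher in CD8 cells, with 12 of 15 risen and 3 not passed (13 risen adjusted over the list alone), among them Rag2 at 3.10 ± 0.18 and Ptcra at 2.54 ± 0.12. The list median was 2.18 (adjusted p = 5.27e-15, held with an estimated correlation). Of 41 cell cycle genes 39 rose and 2 did not pass, also adjusted over the list alone, with a list median of 1.46 (adjusted p = 4.77e-32, but adjusted p = 0.143 with an estimated correlation). CD4 lineage genes gave 11 falls and 4 that did not pass among 15 (12 falls adjusted over the list alone), with Tnfrsf4 at -1.61 ± 0.18 (adjusted p = 1.42e-07, but adjusted p = 0.143 with an estimated correlation). The CD8 lineage list was split, with 4 rises and 2 falls among 20, a median of -0.07 (0.24 with the Cy3 channel alone) and a mean of 0.32, and its test did not pass (adjusted p = 0.334).

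Interferon response genes were lower in thymic CD8 than CD4 cells, where 33 of 44 fell and 11 did not pass (34 fell and 1 rose adjusted over the list alone). Ifih1, a sensor of double-stranded RNA, fell by 1.20 ± 0.11 and Xaf1 by 1.16 ± 0.12. Together they had a median of -0.62 (adjusted p = 5.08e-14, but adjusted p = 0.143 with an estimated correlation). Naive peripheral and egress genes gave 19 falls, 2 rises and 8 that did not pass among 29 (20 and 2 adjusted over the list alone), with Klf2 at -0.87 ± 0.11 and S1pr1 at -1.24 ± 0.18. Across the list the median was -0.50 (adjusted p = 9.56e-07, but adjusted p = 0.157 with an estimated correlation). Regulatory T cell genes gave 13 falls, 2 rises and 2 that did not pass among 17 (14 and 2 adjusted over the list alone), with Tnfrsf18 at -1.13 ± 0.12 and Izumo1r at -1.30 ± 0.18. Members of the list had a median of -1.13 (adjusted p = 5.36e-07, but adjusted p = 0.143 with an estimated correlation). In all 6565 genes passed, 3099 higher and 3466 lower in CD8 cells, but the balance was not stable. It turned with Agilent's processed signals (3206 and 2979), the series matrix values (4029 and 3893), median centring (2110 and 1981), the Cy3 channel alone (3419 and 2932), scan day (3084 and 2639), slide as a fixed (2080 and 1717) or random block (2626 and 2571) and without the later slide (2545 and 2223). The count was 4091 after median centring, 3797 with slide as a fixed block and 2710 when at least 1.5-fold was also required.

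Ageing was the second question of the series, and in CD4 cells of the spleen some genes of antigen-experienced cells were among those higher in old mice. Esm1, which encodes a secreted proteoglycan, rose by 4.74 ± 0.32, adjusted p = 1.63e-07. Ccl5, a chemokine stored by memory cells, rose by 2.84 ± 0.23, adjusted p = 2.2e-06, and Eomes, a transcription factor of memory and cytotoxic cells, by 2.55 ± 0.34, adjusted p = 0.000833. S100a6 rose by 3.29 ± 0.63, adjusted p = 0.0188 and S100a4 by 2.36 ± 0.37, adjusted p = 0.00399. Smad7, an inhibitor of TGF-beta signalling, fell by 1.17 ± 0.19, adjusted p = 0.0061, and Sox4 by 1.40 ± 0.32, adjusted p = 0.0481, and Mir17hg, the host of a microRNA cluster, was lower at -1.50 ± 0.31, adjusted p = 0.0306. All young arrays here lay on slide 1 and all old ones on slide 4, so age and slide coincide. With slide as a random block 16 genes were higher and 1 lower in old mice. With print lot as a covariate S100a6, S100a4 and Mir17hg did not pass (adjusted p = 0.253, 0.205 and 0.217), while Ccl5 did (adjusted p = 0.000777). Print lot also coincides with age in spleen, and only the thymus CD4 groups held both lots. The lot term came from their replicates 3, the old one on the later slide. The values with print lot therefore do not separate lot from age in spleen. Of 33 memory and virtual memory genes 6 rose and 27 did not pass, and 15 rose adjusted over the list alone. The list had a median of 0.71 (adjusted p = 2.85e-11, but adjusted p = 0.63 with an estimated correlation). CD8 lineage genes gave 4 rises and 16 that did not pass among 20 (11 rises adjusted over the list alone), with Cxcr3 at 2.13 ± 0.42 and Nkg7 at 1.02 ± 0.24. The median of the list was 0.87 (adjusted p = 2.93e-10, but adjusted p = 0.61 with an estimated correlation). Cd8a differed by 1.28 ± 0.39 and Cd8b1 by 1.24 ± 0.33, and neither passed. Senescence and secretory genes gave 3 rises and 20 that did not pass among 23 (6 rises and 1 fall adjusted over the list alone), Ccl4 among them at 2.46 ± 0.38. The list median was 0.25, or -0.11 with array print lot as a covariate (adjusted p = 0.00114, but adjusted p = 0.63 with an estimated correlation).

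Markers of other cells moved with these groups in spleen CD4 cells. Erythroid genes had a median of 0.63 (adjusted p = 0.00114, but adjusted p = 0.63 with an estimated correlation), NK and innate-like genes of 0.46, or -0.01 with array print lot as a covariate (adjusted p = 0.0027, but adjusted p = 0.63 with an estimated correlation) and myeloid genes of 0.46 (adjusted p = 0.0154, but adjusted p = 0.63 with an estimated correlation). Old CD4 replicate 3 lay 0.618 of the way from young spleen CD4 to young spleen CD8 cells over 429 genes that part these groups, against 0.250 and 0.129 in replicates 1 and 2. In all 202 genes passed, 132 higher and 70 lower in old mice. The split was 447 and 441 with the series matrix values, 55 and 7 after median centring and 1701 and 2715 with the Cy3 channel alone. With replicate number as a paired replicate block the count was 130, with slide as a random block 17, with array print lot as a covariate 31, and with scan day as a covariate 992. It was 16 in a fit to the 6 arrays alone and 1417 without the later slide. Leaving out young replicate 1, 2 or 3 gave 44, 41 or 48 genes, leaving out old replicate 1, 2 or 3 gave 27, 552 or 654, and leaving out both old spleen replicates 3 gave 683.

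**Figure D2:**
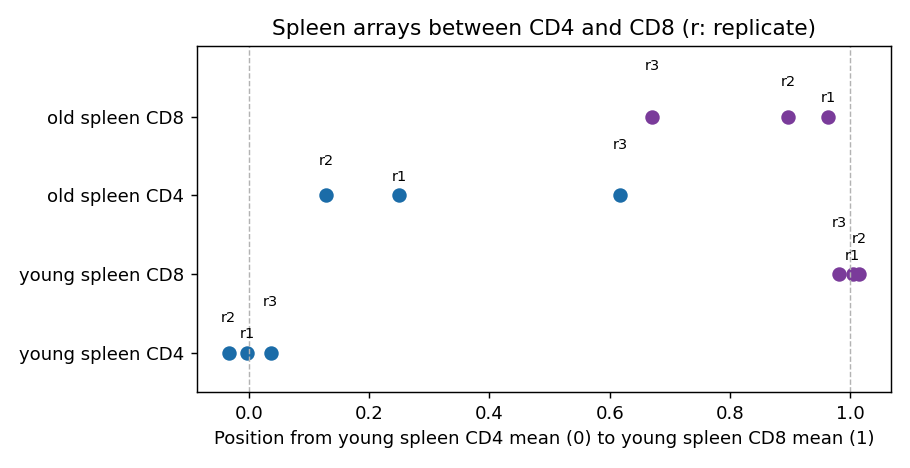
Position of each of the 12 spleen arrays on the axis from the mean of young spleen CD4 (0) to the mean of young spleen CD8 (1) over 429 genes, where each point is 1 array and no error is drawn. Old CD4 replicate 3 (0.618) and old CD8 replicate 3 (0.671) lie next to each other.

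In CD8 cells of the spleen the same comparison of ages gave overlapping genes. S100a6 rose by 3.74 ± 0.63, adjusted p = 0.00912, Esm1 by 2.96 ± 0.32, adjusted p = 6.8e-05, S100a4 by 2.66 ± 0.37, adjusted p = 0.00143 and Ccl5 by 2.55 ± 0.23, adjusted p = 2.75e-05. Casp1, the protease that matures interleukin 1, rose by 1.996 ± 0.218, adjusted p = 6.8e-05, and Fasl, a death ligand of cytotoxic cells, by 1.48 ± 0.30, adjusted p = 0.0281. Sox4 fell by 1.62 ± 0.32, adjusted p = 0.0281, Mir17hg by 1.62 ± 0.31, adjusted p = 0.0264 and Myb, a factor of progenitor cells, by 1.25 ± 0.27, adjusted p = 0.0408. Of 33 memory and virtual memory genes 5 rose and 28 did not pass (10 rose adjusted over the list alone, list median 0.50, adjusted p = 4.83e-07, but adjusted p = 0.929 with an estimated correlation). CD8 lineage genes gave 3 rises and 17 that did not pass among 20 (4 rises adjusted over the list alone), with Cxcr3 at 2.01 ± 0.42. Together they had a median of 0.29, or -0.38 with array print lot as a covariate (adjusted p = 0.00367, but adjusted p = 0.929 with an estimated correlation). NK and innate-like genes moved the same way, with a median of 0.34, or -0.01 with print lot (adjusted p = 0.00427, but adjusted p = 0.929 with an estimated correlation). The rises and falls in CD4 and CD8 cells shared 41 genes higher and 14 lower in old mice, but the 2 comparisons also shared slides 1 and 4.

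In all 153 genes passed in spleen CD8 cells, 99 higher and 54 lower in old mice. The split was 498 and 457 with the series matrix values, 69 and 5 after median centring and 2047 and 2588 with the Cy3 channel alone. The count was 24 with slide as a random block, 26 with array print lot as a covariate, 75 with a replicate block, 709 with scan day as a covariate, 365 in a fit to the 6 arrays alone, 1214 without the later slide and 266 without both old spleen replicates 3. Leaving out young replicate 1 or 2 gave 24 or 27 genes, and leaving out old replicate 1 or 2 gave 32 or 36. The split turned to 68 higher and 76 lower without young replicate 3, 86 and 118 without old replicate 3 and 108 and 158 without both old spleen replicates 3.

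CD4 cells of the thymus, compared between ages, had some thymocyte and memory genes among those higher in old mice. Old replicate 3 lay on the later slide and stood apart from the others, with a correlation as low as 0.610 across genes, which are not independent replicates. With scan day as a covariate Rag1 differed by 1.56 (adjusted p = 0.0104), and the medians of the thymocyte and memory lists were 0.36 and 0.54. Esm1 rose by 3.07 ± 0.32, adjusted p = 1.52e-05, Serpina3g, a protease inhibitor, by 2.88 ± 0.44, adjusted p = 0.000297, Cxcr5, the receptor that guides cells to follicles, by 2.71 ± 0.32, adjusted p = 5.39e-05 and Eomes by 2.70 ± 0.34, adjusted p = 7.53e-05. Per1, a gene of the circadian clock, fell by 2.94 ± 0.40, adjusted p = 0.000136, Bbc3, a pro-apoptotic gene, by 2.14 ± 0.40, adjusted p = 0.0015, and Klf2 by 1.11 ± 0.16, adjusted p = 0.000182. Of 20 thymocyte markers 9 rose and 11 did not pass, also adjusted over the list alone, with Rag1 at 2.57 ± 0.60, Rorc at 1.08 ± 0.17 and Ptcra at 0.89 ± 0.17. Across the list the median was 0.55 (adjusted p = 0.00316, but adjusted p = 0.821 with an estimated correlation). Double-positive thymocyte genes gave 8 rises and 7 that did not pass among 15, also adjusted over the list alone. Members of the list had a median of 0.46 (adjusted p = 0.00362, but adjusted p = 0.661 with an estimated correlation). Memory and virtual memory genes gave 9 rises, 1 fall and 23 that did not pass among 33 (11 and 1 adjusted over the list alone), with Ccl5 at 2.17 ± 0.23, Cxcr3 at 2.35 ± 0.42 and Klrg1 at 1.98 ± 0.36. The list had a median of 0.23, or -0.07 with array print lot as a covariate (adjusted p = 0.0146, but adjusted p = 0.821 with an estimated correlation).

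Members of other groups also passed in old thymic CD4 cells. MHC class I and antigen processing genes gave 3 rises and 13 that did not pass among 16, also adjusted over the list alone, with Psmb8, an immunoproteasome subunit, at 0.67 ± 0.11 and the peptide transporter Tap1 at 0.78 ± 0.18 (adjusted p = 0.00699, but adjusted p = 0.821 with an estimated correlation). Naive peripheral and egress genes split into 4 rises, 4 falls and 21 that did not pass, with S1pr1 at -1.05 ± 0.26 and Il7r, the receptor for interleukin 7, at 0.74 ± 0.21, and the list did not pass (adjusted p = 0.58). Xist, the RNA of the inactive X chromosome, differed by -1.64 ± 0.60 and did not pass (adjusted p = 0.0644). In all 4137 genes passed, 1878 higher and 2259 lower in old mice, and median centring, after which the median of all genes was 0.15, gave 5841 and 478 and shared 1871 calls. The Cy3 channel alone gave 2320 and 2071, and shared 2444 calls, and Agilent's processed signals gave 2031 and 2001. The count was 4142 with scan day as a covariate, and 2935 of the calls were shared. The count was 6423 with the series matrix values, 2477 when at least 1.5-fold was also required and 1118 in a fit to the 6 arrays alone. Leaving out young replicate 1 or 2 gave 2593 or 2053 genes.

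CD8 cells of the thymus were compared between ages last, with all 3 old arrays on the later slide. Syt13, a membrane trafficking gene, rose by 4.83 ± 0.27, adjusted p = 3.12e-09, Rag2 by 3.95 ± 0.25, adjusted p = 9.02e-09, Ptcra by 2.83 ± 0.17, adjusted p = 5.75e-09 and Eomes by 3.55 ± 0.34, adjusted p = 1.02e-06. In the Cy3 channel alone they differed by 0.04 (adjusted p = 0.925), 1.76 (adjusted p = 0.000159), 0.83 (adjusted p = 0.0107) and 2.38 (adjusted p = 0.000413), so that most of the Syt13 ratio lay in the reference channel. With scan day as a covariate, which leaves old thymus CD4 replicate 3 to carry the slide's effect, these 4 differences were 3.48 (adjusted p = 2.69e-05), 3.89 (adjusted p = 0.000386), 2.04 (adjusted p = 0.000269) and 3.22 (adjusted p = 0.0124). Rag1 rose by 4.10 ± 0.60, adjusted p = 8.89e-05, and its difference was 1.097 with scan day (adjusted p = 0.33) and -0.43 with the series matrix values, the opposite sign. Slc2a1, the main glucose transporter, fell by 3.29 ± 0.45, adjusted p = 2.34e-05, Bnip3, a gene of hypoxia and mitophagy, by 3.89 ± 0.53, adjusted p = 2.36e-05, and Il2ra, a receptor chain for interleukin 2, by 2.76 ± 0.39, adjusted p = 2.9e-05. These 3 differences were -0.47 (adjusted p = 0.286), -0.48 (adjusted p = 0.186) and -0.57 (adjusted p = 0.407) with scan day. Of 15 double-positive thymocyte genes 8 rose, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone), with a list median of 1.15, or 1.17 with scan day (camera, adjusted p = 1.53e-06, held with an estimated correlation). The Cy5 reference of this list differed by a median of -1.26, opposite to the ratio and as large, and the median was 0.63 with the Cy3 channel alone. The old samples were not alike. In replicates 1, 2 and 3 the thymocyte marker median was 1.89, 2.75 and 2.77, and Cd4 was -1.43, 1.63 and 0.75. Whether the cells sorted in each sample were the same was not tested. Memory and virtual memory genes gave 15 rises, 4 falls and 14 that did not pass among 33 (16 and 4 adjusted over the list alone), with Gzmm, a granzyme, at 4.78 ± 0.59 and Cxcr3 at 3.58 ± 0.42. The median of the list was 0.52, or 1.40 with scan day (adjusted p = 0.00126, but adjusted p = 0.841 with an estimated correlation).

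Several groups that moved in old thymic CD8 cells shrank once scan day was in the fit. Of 22 glycolysis genes 14 fell, 1 rose and 7 did not pass, also adjusted over the list alone, with Aldoc at -3.09 ± 0.37. The list median was -0.49, or -0.09 with scan day (adjusted p = 0.000425, but adjusted p = 0.568 with an estimated correlation). Regulatory T cell genes gave 10 falls, 2 rises and 5 that did not pass among 17, also adjusted over the list alone, with Tnfrsf9 at -2.76 ± 0.35. Together they had a median of -1.12, or -0.55 with scan day (adjusted p = 0.0139, but adjusted p = 0.841 with an estimated correlation). MHC class I genes gave 10 rises and 6 that did not pass among 16, also adjusted over the list alone, with H2-D1 at 1.16 ± 0.17. Across the list the median was 0.51, or 0.15 with scan day (adjusted p = 0.000836, but adjusted p = 0.525 with an estimated correlation). Markers of other cells moved both ways, with Hbb-b2, a globin gene, at 3.601 ± 0.520, adjusted p = 3.62e-05, or 0.60 with scan day (adjusted p = 0.502), and Dcn, a gene of stroma, at 2.24 ± 0.45, or 0.80 with scan day (adjusted p = 0.564). Lower were Retn, of the stroma and fat list, at -2.05 ± 0.15, or -1.84 with scan day (adjusted p = 0.002), Lum, of the same list and too dim on the old arrays, at least 2.09-fold (adjusted p = 0.000111), and Car1, an erythroid gene, at -1.17 ± 0.26, or -0.11 with scan day (adjusted p = 0.901) and 0.54 with the Cy3 channel alone, the opposite sign. The erythroid list (adjusted p = 0.164) and the stroma and fat list (adjusted p = 0.844) did not pass. Xist was lower at -2.06 ± 0.60, adjusted p = 0.00924, although the arrays overlapped, or -1.36 with scan day (adjusted p = 0.518), and both sexes were used.

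In all 10197 genes passed in thymus CD8 cells, 4245 higher and 5952 lower in old mice. The Cy3 channel alone gave 6207 higher and 6122 lower, and 5600 of the calls were shared. The series matrix values gave 8763 genes, of which 3740 were shared. The count was 609 with scan day as a covariate (313 higher and 296 lower), 2280 with array print lot, 5729 with slide as a random block and 6655 when at least 1.5-fold was also required. Of the genes called, 393 were called in the same direction with scan day.

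**Figure D3:**
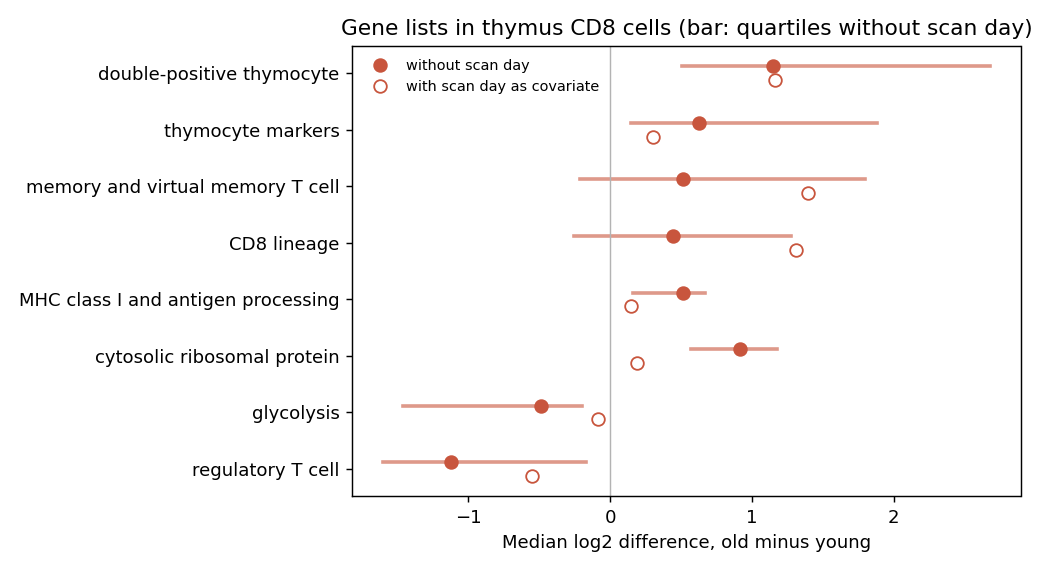
Median log2 age difference in thymus CD8 cells of 8 gene lists, without (filled) and with (open) scan day as a covariate, where each bar spans the lower to upper quartile of the list's genes without the covariate. The double-positive list, whose Cy5 reference differed by a median of -1.26, is at 1.17 with scan day, and the glycolysis list, with a Cy5 median of -0.01, moves from -0.49 to -0.09.

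Whether the age difference itself differed between spleen and thymus was tested next, in CD4 cells. Positive values mean a larger rise, or a smaller fall, with age in spleen. Apex2, a DNA repair nuclease, had a difference of 1.41 ± 0.19, adjusted p = 0.0029, Ecpas, a proteasome adaptor, of 2.12 ± 0.34, adjusted p = 0.00953 and Tsc22d3, a glucocorticoid-induced gene, of 1.24 ± 0.24, adjusted p = 0.0336. Lower were Qpct, at -1.81 ± 0.34, adjusted p = 0.0268, and Tnfrsf1a, a receptor for tumour necrosis factor, at -1.07 ± 0.22, adjusted p = 0.0336. All 19 thymocyte markers missed the threshold over all genes, and 6 were lower adjusted over the list alone. Members of the list had a median of -0.67 (adjusted p = 7.14e-06, but adjusted p = 0.284 with an estimated correlation). CD8 lineage genes were alike in this, with 8 of 20 higher adjusted over the list alone. The list had a median of 0.89 (adjusted p = 0.000312, but adjusted p = 0.871 with an estimated correlation). Cd8a differed by 1.76 ± 0.55 and Klf2 by 0.91 ± 0.22, and neither passed. B cell markers moved with the thymocyte genes, with a median of -0.47 (adjusted p = 0.0189, but adjusted p = 0.871 with an estimated correlation).

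In all 95 genes passed in CD4 cells, 73 positive and 22 negative. The split was 1 and 0 with Agilent's processed signals, 39 and 67 with the series matrix values, 2 and 7 after median centring, with a median of all genes of -0.18, and 97 and 100 with the Cy3 channel alone. The count was 7 with array print lot as a covariate, 9 with slide as a random block, 5 with slide as a fixed block or in a fit to the groups compared alone, 49 with a replicate block, 164 with a stricter filter on dim probes and 302 without the later slide. Leaving out young spleen replicate 1, 2 or 3 gave 10, 14 or 185 genes, young thymus replicate 1, 2 or 3 gave 33, 14 or 29, old spleen replicate 2 or 3 gave 210 or 31, and old thymus replicate 1 or 2 gave 219 or 464.

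The same test of CD8 cells set spleen, scanned on the first day, against old thymus, on the later slide. Esm1 had a difference of 4.001 ± 0.459, adjusted p = 5.63e-05, and Il2ra of 2.78 ± 0.55, adjusted p = 0.00229. The Esm1 value is larger than its rise of 2.96 with age in spleen CD8, so its age difference in thymus CD8 cells was negative. Syt13 had a difference of -5.21 ± 0.38, adjusted p = 4.18e-07 and Rorc, a nuclear receptor of double-positive thymocytes that was too dim on 2 spleen arrays, of -2.45 ± 0.24, adjusted p = 1.12e-05. With the Cy3 channel alone Syt13 (-0.68, adjusted p = 0.169) did not pass. Of 15 double-positive thymocyte genes 9 were lower and 6 did not pass, also adjusted over the list alone, but Rag2 and Ptcra among them were too dim on 6 and 5 of the 6 spleen arrays to give a difference of known size. The median of the list was -1.21, or -1.23 with scan day (adjusted p = 7.69e-08, held with an estimated correlation). The Cy5 medians of the list were -0.06 for age in spleen CD8 and -1.26 in thymus CD8, so the reference differed by about as much in the opposite direction, and the list median was -0.79 with the Cy3 channel alone. Glycolysis genes gave 12 higher, 1 lower and 9 that did not pass among 22 (13 and 1 adjusted over the list alone), with Slc16a3, a lactate carrier, at 3.51 ± 0.64. The list median was 0.65, or 0.15 with scan day (adjusted p = 0.000244, but adjusted p = 0.623 with an estimated correlation). Regulatory T cell genes gave 11 higher, 1 lower and 5 that did not pass among 17 (11 and 2 adjusted over the list alone), with Ctla4 at 2.76 ± 0.50, or -0.34 with the Cy3 channel alone. Together they had a median of 1.43, or 0.58 with scan day (adjusted p = 0.00472, but adjusted p = 0.623 with an estimated correlation). In all 6374 genes passed, 3871 positive and 2503 negative, and the Cy3 channel alone gave 5853 and 5979 and shared 3368 calls. The median of all genes was 0.16 after median centring. The count was 58 with scan day as a covariate (20 and 38), 6 with array print lot (all negative), 2 with slide as a fixed block (both negative), 1044 with slide as a random block and 2211, of which 977 were shared, with the series matrix values.

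By the labels the Cy5 channel held 1 kind of reference RNA, so it served as a control for the age comparisons. Tested in the same way on its own, it gave 6685 genes between young and old spleen CD4 arrays, 6834 for spleen CD8, 2526 for thymus CD4 and 15085 for thymus CD8. For tissue it gave 148 genes in CD4 and 9461 in CD8 cells, and for lineage 2 in spleen and 2490 in thymus. Age by tissue had 11 such genes in CD4 and 14645 in CD8 cells. Across genes, which are not independent replicates, the reference signals of 2 arrays correlated at 0.980 to 0.998 between slides of the first scan day and at 0.936 to 0.951 between the later slide and the others. Whether the later slide received the same preparation of the reference was not tested. The reference was also saturated on that slide for Slc2a1, Bnip3, Aldoc, Tnfrsf9, H2-D1, Slc16a3, Klf2, Klf6, Satb1, Itgb7, Tnfrsf4, Tnfrsf18, Psmb8 and Ccl5, so their differences are not exact wherever old thymus samples enter. Ccl5, Esm1 and the other genes above were measured as ratios to this reference, and ratios remove a reference shift only where sample and reference shift alike.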

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

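The tests of the later slide, of saturated spots, of age with scan day in the model and of swapped, mixed or aged old spleen replicates 3 were chosen only after the results were seen, while the splits of the samples were planned.

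The age difference was tested for a difference between spleen and thymus, and 95 genes passed in CD4 cells and 6374 in CD8 cells. The Cy5 reference, which the labels describe alike for all arrays and which is the denominator of every ratio above, passed the same test for age with 6685 genes in spleen CD4, 6834 in spleen CD8, 2526 in thymus CD4 and 15085 in thymus CD8. Another preparation of the reference on the later slide was not tested and stays open.

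Old and young thymus CD8 cells differed in 10197 genes, and the old arrays all lay on the slide scanned later. Old thymus CD4 replicate 3, on that slide, departed from replicates 1 and 2 in the direction of the CD8 age difference for 86.7% of the genes called, against 44.1%, 48.0% and 54.1% at the 3 other changes of slide within a group. This is consistent with an effect of the slide on most of these genes. Saturated spots as the whole cause are argued against by the 9204 genes called among those with no saturated spot. With scan day as a covariate 393 kept their call and direction, among them Rag2 and Eomes. A single array of CD4 cells then carries the slide's effect, so age and the slide cannot be told apart for these or the other genes.

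Old spleen CD4 and CD8 replicate 3, on different slides, were closer to each other (r = 0.953 across genes, which are not independent replicates, and an SD of the difference of 0.180) than the other 5 pairs with the same number (r from 0.775 to 0.903). A swap of the pair is argued against by the position of the CD8 sample, 0.671 on the axis from young spleen CD4 (0) to CD8 (1). An effect of age as the whole cause is argued against by the other old CD4 replicates, the higher of which lay at 0.250. These replicates 1 and 2, at 0.250 and 0.129, still lay further toward CD8 than the young CD4 samples, at most 0.036. The axis was set by the young samples themselves, so these lie near its ends by construction. The comparison therefore cannot show a shift of the old samples. A smaller shift common to the old CD4 samples stays open. CD4 and CD8 cells mixed in both samples are a candidate explanation, since the share of CD8 signal in the CD4 sample was 0.739 from 48 genes higher in CD8 and 0.580 from 55 genes higher in CD4, with Cd8a at 0.38 and Cd8b1 at 0.94, and the CD8 sample lay further toward CD4 than replicates 1 and 2, at 0.963 and 0.896. The CD8 lineage list, of which other lists hold 13 of 20 genes, rose with age in spleen CD4 cells (adjusted p = 2.93e-10, but adjusted p = 0.61 with an estimated correlation), and a sort on CD4 and CD8 would remove such cells. Shared RNA or a label error outside the pair stays open.

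Other splits of the same arrays, over 21722 genes, show how far chance can be excluded. For age there are 10 splits, too few for a share under 0.05, and the real split gave 186 genes in spleen CD4 (highest other 1), 168 in spleen CD8 (0), 4047 in thymus CD4 (233) and 9616 in thymus CD8 (146). The split with 233 exchanged replicates 3 of thymus CD4 cells, which lie on other slides than replicates 1 and 2. Among 100 splits chance was excluded for tissue in CD4 (2942 genes, highest other 2542), for tissue in CD8 (8742 and 6112) and lineage in the thymus (6435 and 4096). It was also excluded for lineage in the spleen (179 and 237, with 2 splits as large as the real one). For age by tissue the splits are no fair test, since a split that exchanges arrays of 1 tissue keeps the age difference of the other. In CD4 cells chance was not excluded, as 9 of 100 splits gave at least the real 129 genes, but the highest, with 2771, exchanged only spleen arrays and kept the thymus age difference whole. In CD8 cells 3 of 100 were as large (6112 and 6828), which excludes chance only against no age difference in either tissue, and the split with 6828 exchanged the age labels of all thymus arrays. The splits treat arrays as independent, although the correlation within a slide was 0.224 and no slide held both tissues of 1 lineage, and tissue in CD4 had 1646 genes with slide as a random block and 190 as a fixed block, so excluding chance does not exclude the slide. The count was 1 where the real split alone was that large, in the 4 age comparisons, both tissue comparisons and lineage in the thymus.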

How the results depend on the processing

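Scan day, genes with no saturated spot and the fits without the later slide or without both old spleen replicates 3 were chosen only after the results were seen. A count is called moved when it left the range of 1.5 times the value reported, and where nothing else is said the cause was not tested. Quantile normalisation between arrays returned the same values as loess and tests nothing, and a fixed slide block gave no value for the age comparisons, since no slide holds both ages.

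With the series matrix values the counts moved to 888 for age in spleen CD4, 955 in spleen CD8 and 6423 in thymus CD4, 388 for lineage in the spleen and 2211 for age by tissue in CD8, and with Agilent's processed signals to 1 for age by tissue in CD4. Median centring gave 62, 74 and 6319 for age in spleen CD4, spleen CD8 and thymus CD4, 609 for tissue in CD4, 41 and 4091 for lineage in spleen and thymus and 9 for age by tissue in CD4. The Cy3 channel alone gave 4416 and 4635 for age in spleen CD4 and CD8, and 197 and 11832 for age by tissue in CD4 and CD8. The stricter filter, both channels well above background on 18 arrays, gave 164 for age by tissue in CD4. A change of at least 1.5-fold, which is stricter by construction, left 2477 and 6655 for age in thymus CD4 and CD8, 1037 and 4189 for tissue in CD4 and CD8 and 2710 for lineage in the thymus.

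With slide as a random block the counts were 17, 24 and 5729 for age in spleen CD4, spleen CD8 and thymus CD8, 1646 for tissue in CD4, and 9 and 1044 for age by tissue in CD4 and CD8. A fixed slide block gave 190 and 3272 for tissue in CD4 and CD8, 91 and 3797 for lineage in spleen and thymus, and 5 and 2 for age by tissue. Array print lot gave 31, 26 and 2280 for age in spleen CD4, spleen CD8 and thymus CD8, and 7 and 6 for age by tissue. The replicate block gave 130 and 75 for age in spleen CD4 and CD8 and 49 for age by tissue in CD4. A fit to the groups compared alone, with fewer arrays, gave 16, 365 and 1118 for age in spleen CD4, spleen CD8 and thymus CD4 and 5 for age by tissue in CD4. Scan day gave 992, 709 and 609 for age in spleen CD4, spleen CD8 and thymus CD8, 5935 for tissue in CD8, 338 for lineage in the spleen and 58 for age by tissue in CD8. All spleen arrays were scanned on the first day, so this covariate left the differences within the spleen unchanged. Without the later slide the counts were 1417 and 1214 for age in spleen, 526 for lineage in the spleen and 302 for age by tissue in CD4. The list tests past the threshold fell from 116 to 8 with an estimated correlation, as the correlation within lists is then larger.

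Leaving out 1 array at a time gave 27 to 654 genes for age in spleen CD4, 24 to 204 in spleen CD8, 2053 to 4633 in thymus CD4, 104 to 552 for lineage in the spleen and 10 to 464 for age by tissue in CD4, and an arm of the remaining arrays then has fewer samples. Without both old spleen replicates 3 the counts were 683 and 266 for age in spleen and 404 for lineage in the spleen. Age in thymus CD8, both tissue comparisons, lineage in the thymus and age by tissue in CD8 stayed within 1.5 times under each array left out. Of 139 values of named genes, 69 kept sign and side of the threshold under every alternative run. The exceptions in sign were Rag1 in age in thymus CD8, -0.43 with the series matrix values, Car1 in the same comparison, 0.54 with the Cy3 channel alone, and Ctla4 in age by tissue in CD8, -0.34 with the Cy3 channel alone. Dim probes limit what can be seen, as Cy3 stood well above background for at most 69.6% of an array's probes.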

Other observations

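The tests of memory cells among the sorted cells and of scan day were chosen only after the results were seen, unlike those of the reference and of print lot, and the genes named in the next paragraph were chosen after their values were seen.

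Some genes changed with age in all 4 populations. In spleen CD4, spleen CD8, thymus CD4 and thymus CD8 cells together, 24 genes were higher and 8 lower in old mice, of 23655 genes. Ccl5, a chemokine of memory cells, rose by 2.84, 2.55 and 2.17 in the first 3, and in thymus CD8 cells both channels were saturated on the 3 old arrays, so no size is given. Casp1, an inflammatory protease, rose in this order by 1.69, 1.996, 1.99 and 1.72. Psmb8, a subunit of the immunoproteasome, rose by 0.51, 0.47, 0.67 and 0.63, of which the thymus values are not exact, as its reference was saturated on the later slide. Lower were Mir17hg, by -1.50, -1.62, -1.26 and -1.29, and Retn, a hormone gene, by -0.80, -0.94, -1.81 and -2.05. S100a4, S100a6, Serpina3g and Cxcr3 were also among the genes that rose, and Tra2a, Mex3b and Pcm1 among those that fell. In spleen CD4 and CD8 the Cy5 reference of these 3 fell by more than the ratio. Cy5 differed by -1.70 and -1.65 for Tra2a (ratios -0.97 and -0.93) and by -1.60 and -1.59 for Mex3b (-1.43 and -1.19). For Pcm1 it differed by -1.16 and -1.12 (-0.61 and -0.64). It fell by less than the ratio for Mir17hg (-0.79 and -0.80) and rose for Retn (0.77 and 0.72). A slide effect is thus not separated from age for these falls. All spleen arrays were scanned on the first day, so scan day as a covariate could not change the spleen differences. All 32 were still called in both spleen populations, which therefore tests nothing. With this covariate all 32 were also called in thymus CD4 cells. In thymus CD8 cells 13 were called, and Psmb8 (adjusted p = 0.124) and Mir17hg (adjusted p = 0.274) did not pass.

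An opposite shift of the reference would give such a pattern. As the median over the 32 genes, an opposite Cy5 difference made up at most 0.261 of the ratio difference in any of the 4 populations. This argues against it as the whole cause for these 32 genes as a set. The share was above 0.5 in 10 of the 32 genes in thymus CD8 cells, for which an opposite shift stays open. It also stays open for Retn and 1 other gene in both spleen populations, where the share was above 0.5. Choosing 1 direction in all 4 populations would drop genes whose ratio followed a reference shift that reversed between populations. The low share is therefore partly a result of the choice and holds only for these 32 genes. The reference of these genes was not constant. Its median moved along the age direction by 0.65 in spleen CD4, 0.59 in spleen CD8 and 0.53 in thymus CD4, and by -0.30 in thymus CD8 cells. With print lot as a covariate the shared genes kept at least 0.952 of their median difference, although 11, 12, 32 and 25 of the 32 were then called. The lots of young and old arrays were reversed between spleen and thymus CD8 cells. Choosing genes with the same direction in all 4 populations therefore largely fixed this result, and it decides little about lot. Only the thymus CD4 groups held both lots, so their replicates 3 carried the lot term, the old one on the later slide. Memory-phenotype cells among the sorted cells are a candidate explanation, since the memory list rose in all 4 comparisons (camera, largest adjusted p = 0.0146). The list median in thymus CD4 was 0.23, or -0.07 with print lot. With an estimated correlation the adjusted p was 0.63, 0.929, 0.821 and 0.841, and other lists hold 10 of the list's 33 genes. Its members Ccl5, S100a4, S100a6 and Cxcr3 are also among the 32 shared genes. The list test is therefore no independent test of this explanation. Among the list's 5 most abundant members only Ccl5 rose in all 4. Crip1 differed by 0.35, 0.50, 0.27 and 0.56 and Vim by 0.44, 0.34, -0.18 and -0.56, both with a reference saturated on the later slide. Cd44, also a member, differed by 0.21, 0.22, 0.16 and -0.18 and passed in none. The sort for CD44-low cells would remove memory cells. Age stays open as untested since young and old samples shared no slide.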
